A study of Homo sapiens with 9 samples.

How the data were processed

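RNA-seq was analysed from 9 libraries of RKO cells with inducible Cas9, 3 each with a single guide against AAVS1, AKIRIN2 or PSMA3. The labels give Cas9 induction of 2 days for the AAVS1 and AKIRIN2 cells and 3 days for the PSMA3 cells. Per the labels' protocols, RNA was isolated with magnetic beads and libraries were made with an NEBNext Ultra RNA kit and run on a HiSeq2500. Per the submitters' processing notes, the tools were cutadapt 1.4.2, Bowtie2 2.1.0, STAR, featureCounts 1.6.4 and DESeq2 1.22.2, with the genome build GRCh38; their roles, order and settings are not given in the sources used here, nor whether counting used strand. The authors deposited a table of TPM values for 27138 genes by Entrez identifier. The authors also deposited tables of log2 fold changes and adjusted p-values for each knockout against AAVS1, with 13995 genes. Per the file headers these tables hold a mean of the control libraries in RPM, but that column equals the mean control TPM to within a relative difference of 1.9e-08.

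TPM sums to 1000000 in each library and keeps no absolute depth, so absolute depth is unknown. From the steps between low values, where 1 read is the smallest step, depth relative to AAVS1 control replicate 1 was estimated at 0.982 to 1.32 in the other libraries; 33.5% to 40.1% of low genes lay at the ratio of equal counts. The 50 highest genes held 15.3% to 16.2% of TPM in each library. Replicates of a group correlated at 0.986 to 0.991 on the log2 scale, and no library was a copy of another: at most 0.45% of values were identical in a pair.

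All values were analysed as log2(TPM + 1), and fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 1 TPM over the 9 libraries were tested, 12218 in all. A linear model of 3 group means was fitted to all libraries with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance, and p-values were adjusted by Benjamini and Hochberg over the genes of a comparison. A gene was called at an adjusted p under 0.05. There were 3 comparisons. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The tests were tested on simulated data, drawn from the AAVS1 group means with independent noise at the fitted SD of each gene. With 50 genes above 5 TPM changed at each size among 12218, the test of AKIRIN2 against AAVS1 recovered 42%, 94%, 100% and 100% of log2 changes of 0.25, 0.5, 1 and 2, with 9 calls among unchanged genes. The test of PSMA3 against AAVS1 recovered 48%, 94%, 100% and 98%, with 10. Few genes changed in these data, so the adjustment was stricter than where many change. These shares are therefore not the sensitivity of the tests on the real libraries.

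Before the data were examined, 23 gene lists were fixed, among them 20S subunits, 19S subunits, proteasome chaperones with activators and immunoproteasome, ubiquitin shuttles and autophagy receptors, heat shock chaperones, ATF4 targets, unfolded protein response, MYC targets, S phase, G2 and mitosis, NRF2 targets, NF-kB targets, immediate early genes, interferon response, hypoxia, beta-catenin targets, cholesterol synthesis, nuclear import and export, ribosomal proteins, mitochondrially encoded mRNAs, histones, and markers of blood, endothelial and fibroblast cells. Lists were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation. The mitochondrially encoded list had 0 members among the genes analysed, and the 15 cell type markers were all under a mean of 1 TPM. The highest single value among those markers was 1.19 TPM, in HBA1; COL1A1, LYZ and CD14 reached at most 0.322, 0.419 and 0.224 TPM, VWF, CDH5 and PECAM1 at most 0.0458, 0.0581 and 0.031 TPM, while PTPRC, CD3E, HBB, COL1A2, COL3A1, DCN and LUM were listed at 0 in all 9 libraries. The adjustment of list tests therefore covered the remaining 21 lists.

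Genes were named by a rule also fixed before: a set of 13 regulators; for each knockout against AAVS1 the 8 genes that rose and the 8 that fell most, and for AKIRIN2 against PSMA3 the 5 on each side, among genes at adjusted p under 0.05 with a mean of at least 5 TPM in the higher group and no overlap between libraries, leaving out clone, LOC, LINC, pseudogene-style and antisense names; and for each list up to 4 members with the largest change if called or up to 2 with the smallest p if not. The text gives 2 to 4 of a list's picked members as examples, and some genes and 1 list are not reported here, for a reason unrelated to their values, so the lists described are not all of those called. Named from outside the rule, chosen after their values were seen, are PSMD7 in PSMA3 against AAVS1, SLC7A11 against AAVS1, and GLA with the members of the lysosomal and synthetase lists. Symbols follow the deposited table, with older and newer symbols matched through a gene table, which covered 26994 of the 27138 identifiers. Coordinates are from GENCODE on GRCh38, matched through Entrez identifiers.

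Alternatives planned before were other pseudocounts, other minimum means, median-of-ratios, quantile and top-gene scaling, other variance priors, only the groups compared, the replicate number as a block, each library left out, and the authors' tables. A correction of each library for GC content and transcript length, for the 98.1% of tested genes with both, and the 20S list without PSMA3, were added after the data were seen. For the comparison of both responses, 100 draws of 9 libraries without effect, 3 of them shared as controls, were simulated from the residuals of the fit.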

Results

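The libraries came from RKO cells, an established human colon carcinoma line, that carried a Cas9 gene switched on by doxycycline and a guide RNA. Guides were directed at AKIRIN2, a small nuclear protein, at PSMA3, an alpha subunit of the 20S core of the proteasome, or at the AAVS1 locus, which lies in PPP1R12C and served as the control. The labels name a single guide for each target. Effects of a guide outside its target therefore cannot be told apart from loss of the target. Polyadenylated RNA was sequenced from 3 libraries per group, 9 in all. AKIRIN2 and AAVS1 cells were harvested on day 2 after Cas9 induction and PSMA3 cells on day 3, so the day and the target differed together in every comparison that involves PSMA3. The study's title concerns the part of AKIRIN2 in nuclear import of proteasomes, and the comparisons ask how the transcriptome responds to loss of AKIRIN2 and how that response relates to loss of a proteasome subunit. Values are TPM, a measure of transcript abundance scaled to a fixed total in each library, which keeps no absolute depth. Between 14418 and 14998 genes were above 0 in a library. Tests covered the 12218 genes with a mean of at least 1 TPM. The labels do not state separate cultures, so the p-values measure only the spread between these samples. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and are given with their standard error. Every gene named singly as having risen or fallen had all 3 libraries of 1 group beyond all 3 of the other.

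AKIRIN2 mRNA was at 46.5 ± 1.13 TPM (SD, n = 3) in the AAVS1 libraries, 17.9 ± 0.305 TPM in the AKIRIN2 libraries and 43.6 ± 2.55 TPM in the PSMA3 libraries. It fell by 1.33 on the log2(TPM + 1) scale in the AKIRIN2 libraries (SE 0.05, limma, Benjamini-Hochberg adjusted p = 1.13e-07), and its log2 fold change in the PSMA3 libraries was -0.09 ± 0.05 (adjusted p = 0.111, limma, Benjamini-Hochberg). Without PSMA3 knockout replicate 2 that value was -0.14 and passed (adjusted p = 0.0227, in a range of 0.0227 to 0.965 over all alternatives). PSMA3 mRNA was at 367 ± 10.9 TPM in the AAVS1 libraries and 178 ± 3.67 TPM in the PSMA3 libraries, a log2 fold change of -1.04 ± 0.03 (limma, Benjamini-Hochberg adjusted p = 1.87e-08). It also fell in the AKIRIN2 libraries, to 273 ± 9.07 TPM (log2 fold change -0.42 ± 0.03, limma, Benjamini-Hochberg adjusted p = 8.43e-06). Every library of a targeted group was below every control library for its targeted gene. In GRCh38, AKIRIN2 (Entrez 55122) lies on chromosome 6 from 87675072 to 87702209 on the minus strand. PSMA3 (Entrez 5684) lies on chromosome 14 from 58244831 to 58272012 on the plus strand, and PPP1R12C (Entrez 54776) on chromosome 19 from 55090913 to 55117559 on the minus strand. PPP1R12C, which holds the control locus, was at 52.3 ± 4.46 TPM in the AAVS1 libraries, 63.0 ± 0.767 in the AKIRIN2 libraries and 53.7 ± 2.11 in the PSMA3 libraries.

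**Figure D1:**
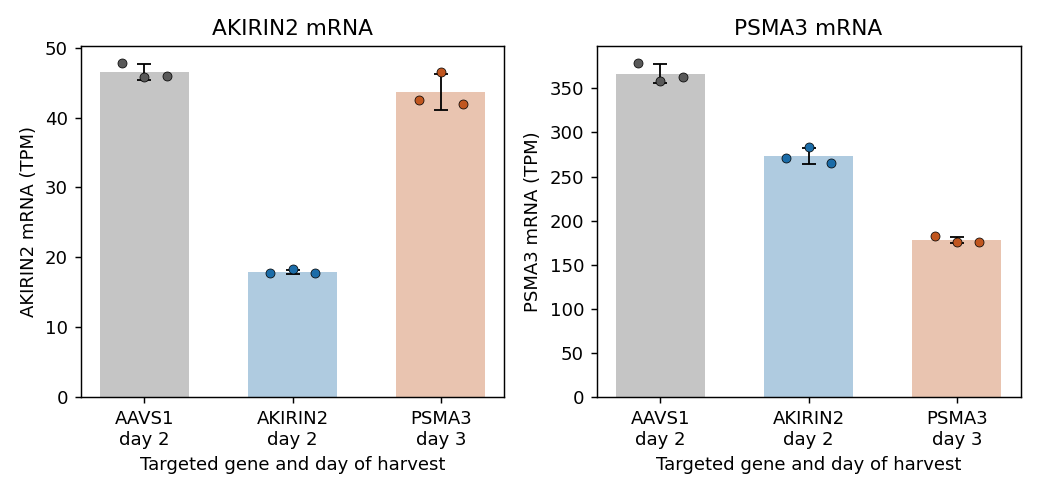
TPM of AKIRIN2 (left) and PSMA3 (right) in each library (points), with the group mean (bar) and SD (error bar, n = 3), by targeted gene and day of harvest. AKIRIN2 mRNA averaged 46.5 TPM in the AAVS1 and 17.9 TPM in the AKIRIN2 libraries, and PSMA3 mRNA 367 TPM in the AAVS1 and 178 TPM in the PSMA3 libraries.

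Against AAVS1, the AKIRIN2 libraries had a large rise in GDF15, a stress-induced cytokine. It went from 2.78 ± 0.503 to 90.6 ± 6.13 TPM (SD, n = 3), a log2 fold change of 4.60 ± 0.09 (limma, Benjamini-Hochberg adjusted p = 5.2e-09).

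Among the lists reported here, NF-kB targets and interferon response genes were higher in the AKIRIN2 libraries. Of 16 NF-kB targets 14 rose and 1 fell, the same numbers adjusted over the list alone, led by BIRC3, an inhibitor of apoptosis (log2 fold change 1.78 ± 0.05), TRAF1, an adaptor of TNF receptors (from 2.66 to 10.1 TPM), and TNFAIP3, a negative regulator of the pathway (from 3.95 to 12.9 TPM). Of 14 interferon response genes 12 rose and 0 fell, also 12 adjusted over the list alone, with IFIH1, a sensor of double-stranded RNA, at 1.36 ± 0.11 and IFI6 at 1.12 ± 0.17. The camera adjusted p was 1.19e-05 for the NF-kB list and 0.000314 for the interferon list (limma, Benjamini-Hochberg), and each had adjusted p = 0.0564 with an estimated correlation.

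Genes of G2 and mitosis fell in the AKIRIN2 libraries. All 21 members were lower, also 21 adjusted over the list alone, with a median log2 fold change of -0.48. PLK1, a mitotic kinase, was at -0.70 ± 0.06, CENPE, a kinetochore motor, at -0.67 ± 0.06, and the proliferation marker MKI67 at -0.66 ± 0.04 (camera in limma, Benjamini-Hochberg adjusted p = 1.08e-11, and adjusted p = 0.306 with an estimated correlation). Of 21 genes of DNA replication and S phase 10 fell and 2 rose, also 10 and 2 adjusted over the list alone, and the list was not called (limma camera, Benjamini-Hochberg adjusted p = 0.0514, in a range of 0.00327 to 0.652 over all alternatives). It was called as lower without AAVS1 control replicate 2, AKIRIN2 knockout replicate 1, PSMA3 knockout replicate 1 or PSMA3 knockout replicate 2 (adjusted p = 0.00327, 0.0286, 0.0464 and 0.0478). It was also called so with no filter on the mean, the GC and length correction, the replicate number as a block or top-gene scaling (limma camera, Benjamini-Hochberg adjusted p = 0.0227, 0.036, 0.0312 and 0.0485). The members that rose were PCNA, the sliding clamp of DNA polymerase, at 0.44 ± 0.05, and CCNE1 at 0.33 ± 0.04.

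Heat shock chaperones fell. Of 19 measured members 13 were lower and 1 higher, the same numbers adjusted over the list alone, with a median log2 fold change of -0.19 and the largest falls in CHORDC1 (-0.44 ± 0.06), HSPH1 (-0.41 ± 0.07) and DNAJB1 (-0.39 ± 0.05). The list had a camera adjusted p of 0.000236 (limma, Benjamini-Hochberg), and adjusted p = 0.507 with an estimated correlation. Of 21 ATF4 and integrated stress response targets 11 fell and 6 rose, as many adjusted over the list alone. ASNS, asparagine synthetase, went from 527 to 120 TPM (-2.13 ± 0.13), and the serine synthesis enzymes PHGDH and PSAT1 fell by 1.28 and 1.16, while SESN2, a stress-induced regulator of growth signalling, rose by 1.33 ± 0.08. That list was called (limma camera, Benjamini-Hochberg adjusted p = 0.0238) but not with an estimated correlation (adjusted p = 0.507 with an estimated correlation), nor under median-of-ratios scaling (adjusted p = 0.0502) or quantile normalization (adjusted p = 0.0858), in a range of 0.0149 to 0.507 over all alternatives.

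The proteasome subunits themselves moved little in the AKIRIN2 libraries and in both directions. Of 14 20S core subunits 7 rose and 3 fell, and of 19 subunits of the 19S regulatory particle 3 rose and 8 fell, against 7 and 3, and 4 and 8, adjusted over the list alone. PSMB5, which carries the chymotrypsin-like site, was at 0.24 ± 0.02, and PSMD7 at -0.40 ± 0.04. Neither list was called (limma camera, Benjamini-Hochberg adjusted p = 0.552 and 0.0798), though the 19S list was called as lower under median-of-ratios scaling (adjusted p = 0.044), without AAVS1 control replicate 2 (adjusted p = 0.0472) and without AKIRIN2 knockout replicate 1 (adjusted p = 0.035), in a range of 0.035 to 0.652 over all alternatives. The 19S list was also called as lower after the GC and length correction and with no filter on the mean (limma camera, Benjamini-Hochberg adjusted p = 0.036 and 0.0398). Among 17 proteasome chaperones, activators and immunoproteasome genes 8 rose and 5 fell, as many adjusted over the list alone. PSME1 and PSME2, subunits of the 11S activator, rose by 0.68 ± 0.03 and 0.75 ± 0.04.

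EGR1 and EGR3, transcription factors of the immediate early class, went from 289 to 109 and from 30.6 to 11.8 TPM in the AKIRIN2 libraries, and TAGLN, an actin-binding protein, fell by 1.51. Immediate early genes as a list were not called (9 lower and 6 higher of 19, the same adjusted over the list alone, limma camera, Benjamini-Hochberg adjusted p = 0.096). HMOX1, the haem-degrading enzyme, rose by 2.22 ± 0.08 while GCLM, a subunit of the first enzyme of glutathione synthesis, fell by 0.82. Of the 16 NRF2 oxidative stress targets 6 rose and 5 fell, with 7 and 5 adjusted over the list alone. Other large rises were in EPS8L2 (2.71 ± 0.11), WDR63 (2.82 ± 0.14) and LCE1F (2.71 ± 0.38). MYH16, a myosin gene with a disrupted reading frame in humans, rose by 3.79 ± 0.11. MIR320E (3.12 ± 0.55) and MIR4426 (-1.41 ± 0.31) also passed, but reads of such short genes cannot be told from overlapping transcripts, so their values are uncertain. SNORD49B (2.50 ± 0.90), MIR4786 (-2.14 ± 0.69) and MIR6807 (-1.31 ± 0.47) had adjusted p of 0.0406, 0.0248 and 0.0399 (limma, Benjamini-Hochberg), with ranges of 0.00415 to 0.117, 0.00866 to 0.0832 and 0.00384 to 0.0956 over all alternatives. SNORD49B lost its call without AAVS1 control replicate 1 or 2 or AKIRIN2 knockout replicate 1, 2 or 3 (adjusted p = 0.117, 0.117, 0.0826, 0.0878 and 0.0859), and MIR4786 without AAVS1 control replicate 1 or 3 or AKIRIN2 knockout replicate 1 or 2 (adjusted p = 0.0781, 0.0675, 0.0832 and 0.0826). MIR6807 lost it without any 1 control library, any 1 PSMA3 library or AKIRIN2 knockout replicate 1 (adjusted p = 0.0535 to 0.0941).

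In the AKIRIN2 libraries higher and lower members were also 25 and 1 of 75 cytosolic ribosomal protein genes (23 and 0 adjusted over the list alone). They were 9 and 3 of 21 ubiquitin shuttles and autophagy receptors, 4 and 8 of 18 unfolded protein response genes, and 11 and 11 of 34 MYC targets. They were also 2 and 6 of 13 hypoxia genes, 0 and 2 of 5 beta-catenin targets, 4 and 2 of 15 cholesterol synthesis genes, 6 and 9 of 24 nuclear import and export factors, and 6 and 3 of 13 histone genes, in each case the same numbers adjusted over the list alone. Of these the ribosomal list was called, as higher (median log2 fold change 0.08, limma camera, Benjamini-Hochberg adjusted p = 0.0238, and adjusted p = 0.694 with an estimated correlation). Its call had a range of 0.00012 to 0.694 over all alternatives. It was lost under median-of-ratios scaling (adjusted p = 0.175) and without AAVS1 control replicate 1, AAVS1 control replicate 3 or AKIRIN2 knockout replicate 3 (adjusted p = 0.0689, 0.181 and 0.23). The medians of the chaperone and activator, MYC and NRF2 lists changed sign under at least 1 other scaling, that of the ubiquitin shuttle list only after the GC and length correction, and the MYC list had a median of -0.01 and a mean of 0.01.

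Among the regulators chosen singly, AKIRIN1, the paralog of AKIRIN2, rose by 0.33 ± 0.04 and NFE2L1, a regulator of proteasome genes, by 0.34 ± 0.04 in the AKIRIN2 libraries. IPO9, a nuclear import receptor, fell by 0.18, MYC by 0.20 and HIF1A, the hypoxia factor, by 0.23. PPP1R12C rose by 0.27 ± 0.06, while HSF1, the heat shock factor, and NGLY1 did not pass (0.08 ± 0.04 and -0.05 ± 0.04), though HSF1 did without PSMA3 knockout replicate 1 (adjusted p = 0.048, limma, Benjamini-Hochberg, in a range of 0.0462 to 0.501 over all alternatives). NFE2L2, which encodes NRF2, was at 0.12 ± 0.04 (limma, Benjamini-Hochberg adjusted p = 0.0367, in a range of 0.0111 to 0.168 over all alternatives). Its call was lost without AAVS1 control replicate 2 or 3 (adjusted p = 0.119 and 0.0861), AKIRIN2 knockout replicate 1, 2 or 3 (0.0995, 0.0745 and 0.062) or PSMA3 knockout replicate 3 (0.0537). Median-of-ratios scaling, quantile normalization and the GC and length correction also ended that call (adjusted p = 0.168, 0.0763 and 0.136, limma, Benjamini-Hochberg). CTNNB1, beta-catenin, was at -0.09 ± 0.03 (limma, Benjamini-Hochberg adjusted p = 0.0285, in a range of 0.00209 to 0.213 over all alternatives). Its call was lost without AAVS1 control replicate 1 or 3 (adjusted p = 0.0589 and 0.103) or AKIRIN2 knockout replicate 2 or 3 (0.0708 and 0.0994). Quantile normalization also ended it (adjusted p = 0.213, limma, Benjamini-Hochberg).

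Across all genes, 3739 were higher and 2632 lower in the AKIRIN2 libraries at a limma Benjamini-Hochberg adjusted p under 0.05. Of these, 170 and 28 changed by at least 1 on the log2 scale, and the median absolute log2 fold change of called genes was 0.31. The share of higher calls was 58.7%, and 49.2% under median-of-ratios scaling or 48.0% after a correction for GC content and length. The authors' deposited table lists 2862 genes as higher and 3010 as lower at the same threshold.

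In the PSMA3 libraries, harvested 1 day later than the controls, mRNAs of the proteasome rose throughout the complex. Of 14 20S core subunits 13 were higher, and 1, the targeted PSMA3, was lower. PSMB3 and PSMB2, beta subunits of the core, rose by 1.06 ± 0.05 and 1.04 ± 0.04 on the log2 scale. Of 19 subunits of the 19S particle 18 rose and 0 fell, led by the ATPase PSMC4, from 183 to 475 TPM (1.37 ± 0.04), and PSMC6 (1.14 ± 0.04). PSMD7, at 0.08 ± 0.04, did not pass. These counts were the same adjusted over the list alone. Medians were 0.75 and 0.70 (limma camera, Benjamini-Hochberg adjusted p = 3.98e-07 and 1.13e-10), with adjusted p = 0.111 and adjusted p = 0.0688 with an estimated correlation. Among 17 chaperones, activators and immunoproteasome genes 8 rose and 5 fell, as many adjusted over the list alone, and that list was not called (limma camera, Benjamini-Hochberg adjusted p = 0.156).

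**Figure D2:**
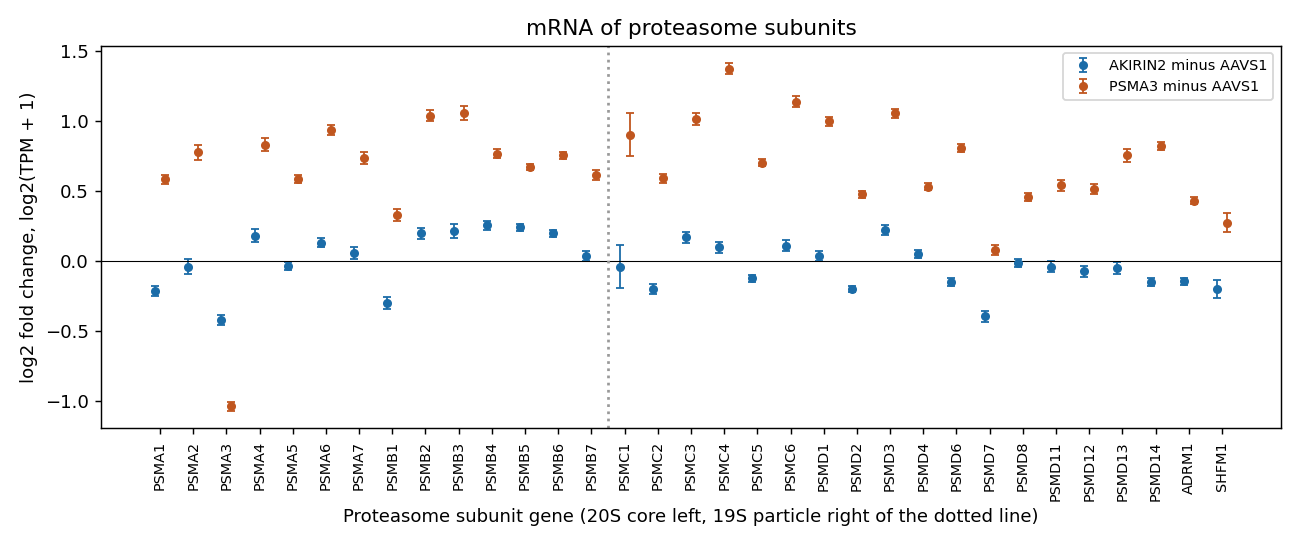
Log2 fold change on the log2(TPM + 1) scale against AAVS1 (points) with its standard error (bars, n = 3 per group) for 33 proteasome subunit genes, in the AKIRIN2 and the PSMA3 libraries; SHFM1 is the older symbol of SEM1. In the PSMA3 libraries 31 of the 33 rose, and in the AKIRIN2 libraries 10 rose and 11 fell.

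Ubiquitin shuttles and autophagy receptors rose with the proteasome in the PSMA3 libraries. Of 21 members 18 were higher and 1 lower, the same numbers adjusted over the list alone, with a median log2 fold change of 0.63. GABARAPL1, a protein of the autophagosome membrane, went from 22.9 ± 3.17 to 158 ± 3.33 TPM (SD, n = 3), a log2 fold change of 2.74 ± 0.09. ZFAND2A, a stress-induced proteasome-associated protein, rose by 1.99 ± 0.09. The list was called with the preset correlation (limma camera, Benjamini-Hochberg adjusted p = 9.25e-08) and with an estimated one (adjusted p = 0.0258 with an estimated correlation).

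Heat shock chaperones and NRF2 targets were higher in the PSMA3 libraries. Of 19 chaperones 14 rose and 3 fell, with 15 and 3 adjusted over the list alone. DNAJB4 rose by 1.38 ± 0.07 and BAG3, a co-chaperone, by 0.98 ± 0.08. HSPA1B went from 45.5 to 139 TPM, a value that is uncertain because its reads are shared with the near-identical HSPA1A. Of 16 NRF2 targets 13 rose and 0 fell, with 13 and 1 adjusted over the list alone. HMOX1 went from 71.0 ± 10.6 to 510 ± 18.4 TPM (2.84 ± 0.08), and GCLM rose by 1.33 ± 0.06. The camera adjusted p was 0.000557 and 9.14e-05 (limma, Benjamini-Hochberg), with adjusted p = 0.387 and adjusted p = 0.0622 with an estimated correlation. NFE2L2 rose by 0.71 ± 0.04, NFE2L1 by 0.32 ± 0.04, and NGLY1, which deglycosylates the NFE2L1 protein, by 0.41 ± 0.04.

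The NF-kB and interferon lists were higher in the PSMA3 libraries too. Of 16 NF-kB targets 12 rose and 2 fell, and of 14 interferon genes 11 rose and 1 fell, each as many adjusted over the list alone. CXCL8, a neutrophil chemokine, rose by 2.76 ± 0.16, and MX1, an antiviral GTPase, by 1.39 ± 0.09. IFI44 went from 0.368 ± 0.0774 to 17.4 ± 1.26 TPM, a log2 fold change of 3.75 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 1.88e-08). The camera adjusted p was 0.000855 and 0.000751 (limma, Benjamini-Hochberg), with adjusted p = 0.0877 and adjusted p = 0.0622 with an estimated correlation.

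Genes of the cell cycle fell in the PSMA3 libraries. All 21 genes of G2 and mitosis were lower, with a median log2 fold change of -1.03, and PLK1 went from 114 to 36.4 TPM (-1.62 ± 0.06). Of 21 S phase genes 15 fell and 1 rose, with E2F1 at -0.88 ± 0.06. Of 19 immediate early genes 14 fell and 2 rose, with EGR1 going from 289 ± 10.3 to 62.5 ± 2.09 TPM (-2.19 ± 0.04) and EGR3 at -2.19 ± 0.06. These counts were the same adjusted over the list alone. The 3 lists had camera adjusted p of 3.89e-10, 0.000957 and 0.00138 (limma, Benjamini-Hochberg), and adjusted p = 0.158, adjusted p = 0.39 and adjusted p = 0.14 with an estimated correlation. Beta-catenin targets were lower in 4 of 5, and 5 adjusted over the list alone, with TCF7 at -1.04 ± 0.07 and LEF1, a transcription factor of the pathway, going from 36.0 to 17.6 TPM (limma camera, Benjamini-Hochberg adjusted p = 0.0427, and adjusted p = 0.156 with an estimated correlation). That call was lost without AAVS1 control replicate 1, AAVS1 control replicate 2 or PSMA3 knockout replicate 1 (adjusted p = 0.0512, 0.0531 and 0.0517) and with quantile normalization (adjusted p = 0.0507), in a range of 0.014 to 0.156 over all alternatives.

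Cholesterol synthesis genes rose in the PSMA3 libraries. Of 15 members 10 were higher and 2 lower, with 11 and 2 adjusted over the list alone, and HMGCS1, an early enzyme of the pathway, rose by 0.87 ± 0.06 (limma camera, Benjamini-Hochberg adjusted p = 0.00795, and adjusted p = 0.249 with an estimated correlation). Of 75 ribosomal protein genes 25 rose and 8 fell, with 22 and 5 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0427, and adjusted p = 0.746 with an estimated correlation). The ribosomal call was lost with quantile normalization (adjusted p = 0.169) and without AAVS1 control replicate 1, AAVS1 control replicate 3 or PSMA3 knockout replicate 1 (adjusted p = 0.0769, 0.2 and 0.117), in a range of 0.000771 to 0.746 over all alternatives. ASNS fell by 2.24, PHGDH by 1.80 and TAGLN by 1.84, while DDIT3, which encodes the stress factor CHOP, rose by 1.27 ± 0.05. GDF15 reached 26.9 ± 1.19 TPM (2.89 ± 0.09). GPX3, a secreted glutathione peroxidase, rose by 2.95 ± 0.09 and STYK1 by 2.69 ± 0.17, and PSRC1, a spindle protein, went from 43.4 to 11.9 TPM. MIR616 (2.55 ± 0.41) and MIR6791 (-2.15 ± 0.47) passed, with the same uncertainty as other short genes. SNORA50C (-1.88 ± 0.67, limma, Benjamini-Hochberg adjusted p = 0.0304, in a range of 0.00404 to 0.0884 over all alternatives) lost its call without AAVS1 control replicate 1 or 2 (adjusted p = 0.0884 and 0.0615). Higher and lower members were 7 and 10 of 21 ATF4 targets, 10 and 5 of 18 unfolded protein response genes and 8 and 18 of 34 MYC targets. They were also 4 and 7 of 13 hypoxia genes, 4 and 8 of 24 import factors and 2 and 5 of 13 histone genes, the same numbers adjusted over the list alone, and none of these 6 lists was called by limma camera (Benjamini-Hochberg adjusted p from 0.113 to 0.755). The medians of the ATF4 and import lists changed sign under another scaling, and the histone list had a median of 0.02 and a mean of -0.06.

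Of the other regulators, AKIRIN1 rose by 0.38 ± 0.04 and HSF1 by 0.13 ± 0.04 in the PSMA3 libraries, and IPO9 fell by 0.18 and MYC by 0.17. PPP1R12C did not pass (0.04 ± 0.06). HIF1A was at -0.13 ± 0.04 (limma, Benjamini-Hochberg adjusted p = 0.0151, in a range of 0.00171 to 0.0624 over all alternatives), and its call was lost without AAVS1 control replicate 3 or PSMA3 knockout replicate 3 (adjusted p = 0.0624 and 0.0565). CTNNB1, at -0.06 ± 0.03 (adjusted p = 0.0963, limma, Benjamini-Hochberg, in a range of 0.0255 to 0.56 over all alternatives), passed without AAVS1 control replicate 2 (adjusted p = 0.0469).

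Across all genes, 3759 were higher and 4458 lower in the PSMA3 libraries at a limma Benjamini-Hochberg adjusted p under 0.05. Of these, 278 and 267 changed by at least 1 on the log2 scale. The share of higher calls was 45.7%, and 51.0% under median-of-ratios scaling, so which direction had more calls rests on the scaling. The authors' deposited table lists 3987 genes as higher and 3815 as lower. No control library of day 3 was used here, so the day and the loss of PSMA3 cannot be told apart.

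Set directly against each other, the AKIRIN2 and PSMA3 libraries differed most evenly in the proteasome genes. Of the 33 subunits 32 were lower in the AKIRIN2 libraries, and 1, PSMA3, was higher, with a median log2 difference of -0.68. PSMC4 was at 196 TPM in the AKIRIN2 and 475 TPM in the PSMA3 libraries (-1.28 ± 0.04), and PSMD14, the deubiquitinase of the 19S particle, was at -0.97 ± 0.03. All 19 members of the 19S list were lower, also 19 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.98e-21, and adjusted p = 0.0216 with an estimated correlation). Of the 20S list 13 were lower and 1 higher, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 2.06e-12, and adjusted p = 0.0544 with an estimated correlation). Of the 17 chaperones, activators and immunoproteasome genes 6 were higher and 3 lower, as many adjusted over the list alone, without a call (median 0.06, test direction down).

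Several other lists lay on the same side. Of 21 ubiquitin shuttles and autophagy receptors 16 were lower and 2 higher in the AKIRIN2 libraries, with GABARAPL1 at -2.25 ± 0.09, and of 16 NRF2 targets 11 were lower and 0 higher, with GCLM at -2.16 ± 0.06 and NQO1 at -0.79 ± 0.04. Both lists were called by limma camera (Benjamini-Hochberg adjusted p = 2.58e-11 and 1.01e-07), also with an estimated correlation (adjusted p = 0.00873 and adjusted p = 0.0216). Of 19 heat shock chaperones 15 were lower and 1 higher, with BAG3 at -1.22 ± 0.08, of 18 unfolded protein response genes 8 were lower and 2 higher, with HSPA5 at -0.56 ± 0.03, and of 15 cholesterol synthesis genes 11 were lower and 1 higher. These counts were the same adjusted over the list alone. Those 3 lists had camera adjusted p of 1.09e-11, 0.000494 and 9.35e-05 (limma, Benjamini-Hochberg), and adjusted p = 0.17, adjusted p = 0.223 and adjusted p = 0.17 with an estimated correlation. SLC7A11, the cystine transporter, was at 9.93 TPM in the AKIRIN2 libraries, 19.9 in the AAVS1 and 47.5 in the PSMA3 libraries.

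Among the lists on the other side were those of the cell cycle, which were higher in the AKIRIN2 than in the PSMA3 libraries. Of 21 genes of G2 and mitosis 19 were higher and 0 lower, with 19 and 1 adjusted over the list alone, and of 21 S phase genes 15 were higher and 1 lower. Of 19 immediate early genes 12 were higher and 0 lower, with DUSP5 at 0.77 ± 0.03, and of 13 histone genes 8 were higher and 0 lower. The other counts were the same adjusted over the list alone. The camera adjusted p of these 4 lists, in that order, was 1.53e-06, 0.00348, 0.00207 and 0.0279 (limma, Benjamini-Hochberg). With an estimated correlation they were adjusted p = 0.261, adjusted p = 0.433, adjusted p = 0.173 and adjusted p = 0.259, and the histone call was also lost without AKIRIN2 knockout replicate 1 (adjusted p = 0.0588, in a range of 0.00827 to 0.259 over all alternatives). Several histone genes are near-identical copies, so their single values are uncertain. The histone list was fixed as a check on poly(A) selection, and a difference in selection cannot be told apart from one in expression.

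Lists without a call between the AKIRIN2 and PSMA3 libraries had higher and lower members of 6 and 7 of 21 ATF4 targets, 17 and 4 of 34 MYC targets, and 8 and 4 of 16 NF-kB targets. They also had 4 and 3 of 14 interferon genes, 6 and 2 of 13 hypoxia genes and 4 and 0 of 5 beta-catenin targets, the same numbers adjusted over the list alone. Of 24 import factors 6 were higher and 3 lower, and of 75 ribosomal protein genes 11 and 5, with 5 and 3 and 8 and 4 adjusted over the list alone. The medians of the chaperone and activator, interferon, hypoxia, import and ribosomal lists changed sign under another scaling. Median and mean differed in sign for the interferon (0.01 and -0.29) and import (-0.01 and 0.01) lists, and the ribosomal list (median 0.03) was tested as lower. The ATF4 list (limma camera, Benjamini-Hochberg adjusted p = 0.0599, in a range of 0.0386 to 0.353 over all alternatives) was called as lower without AKIRIN2 knockout replicate 2, AKIRIN2 knockout replicate 3 or PSMA3 knockout replicate 3 (adjusted p = 0.0478, 0.0416 and 0.0457). It was also called so after the GC and length correction (adjusted p = 0.0386). The MYC list was called as higher with quantile normalization or no filter (adjusted p = 0.00561 and 0.0454, limma camera, Benjamini-Hochberg, in a range of 0.00561 to 0.883 over all alternatives). The beta-catenin list was called as higher under median-of-ratios scaling, without a trend or after the GC and length correction (adjusted p = 0.0366, 0.0218 and 0.0386, in a range of 0.0218 to 0.223 over all alternatives). Import factors were called as lower under median-of-ratios scaling (adjusted p = 0.0366, in a range of 0.0366 to 0.864 over all alternatives). IFI44, at -3.65 ± 0.12, and MX1, at -1.04 ± 0.09, were lower in the AKIRIN2 than in the PSMA3 libraries. So were GADD45G (-2.62 ± 0.27), PIR (-2.39 ± 0.17) and MLLT11 (-2.27 ± 0.10), while GDF15 (1.72 ± 0.09), PLAT, tissue plasminogen activator (1.81 ± 0.15), MYH16 (1.83 ± 0.11) and TMEM158 (1.36 ± 0.14) were higher. LCE1F was at 1.34 ± 0.38, and its call was lost without AKIRIN2 knockout replicate 1 or 2 (adjusted p = 0.0536 and 0.0502, limma, Benjamini-Hochberg, in a range of 0.00266 to 0.0565 over all alternatives).

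Regulators that differed between these groups besides the targeted genes were PPP1R12C (0.23 ± 0.06), higher in the AKIRIN2 libraries, and NFE2L2 (-0.60 ± 0.04) and NGLY1 (-0.46 ± 0.04), lower there. The PPP1R12C difference was lost under median-of-ratios scaling (adjusted p = 0.0683, limma, Benjamini-Hochberg, in a range of 0.00184 to 0.15 over all alternatives). AKIRIN1, IPO9, MYC, NFE2L1, HSF1, HIF1A and CTNNB1 did not pass. Under median-of-ratios scaling, however, AKIRIN1, MYC, HSF1 and CTNNB1 passed as lower (adjusted p = 0.0123, 0.0122, 0.0097 and 0.00511, limma, Benjamini-Hochberg). They did so after the GC and length correction too (adjusted p = 0.0317, 0.00299, 0.000243 and 0.0288), as did NFE2L1 (adjusted p = 0.0368), so the absence of a call depends on the scaling and the correction. Their adjusted p were in a range of 0.0123 to 0.621, 0.00299 to 0.913, 0.000243 to 0.88, 0.00511 to 0.801 and, for NFE2L1, 0.0368 to 0.857 over all alternatives. HIF1A (-0.10 ± 0.04) passed as lower in both settings (adjusted p = 0.00172 and 0.028) and without AAVS1 control replicate 2 or 3 (adjusted p = 0.037 and 0.0451, limma, Benjamini-Hochberg, in a range of 0.00172 to 0.186 over all alternatives).

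**Figure D3:**
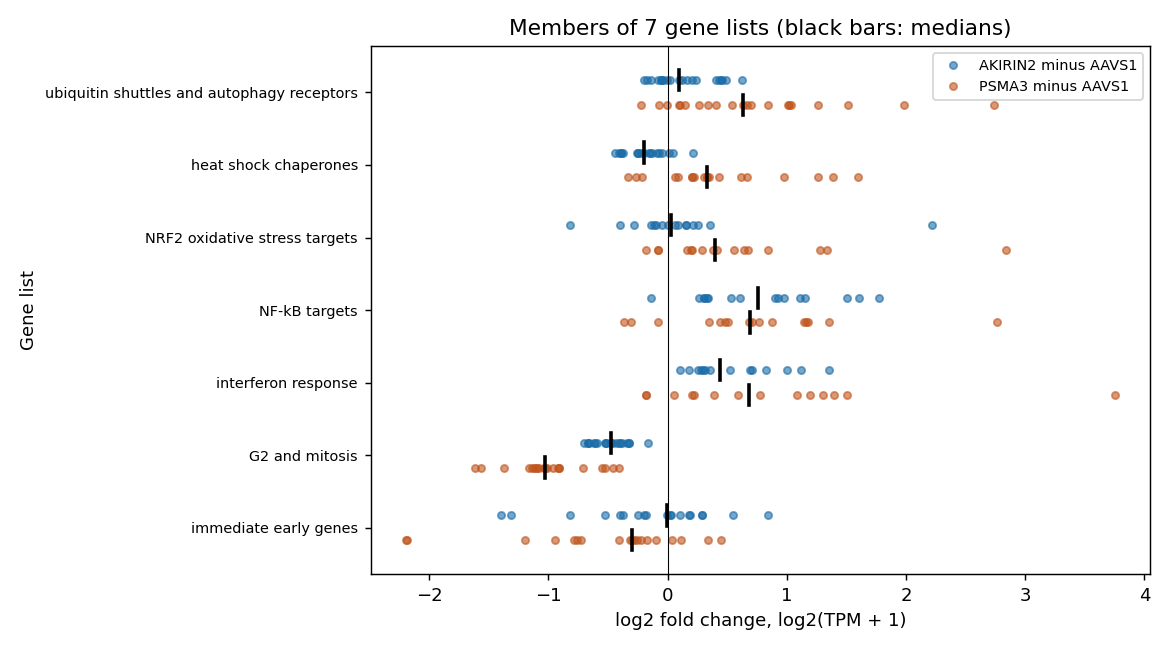
Log2 fold change on the log2(TPM + 1) scale against AAVS1 of each tested member (points) of 7 gene lists in the AKIRIN2 and the PSMA3 libraries, with the list median (black bar). The median of the heat shock chaperones was -0.19 in the AKIRIN2 and 0.33 in the PSMA3 libraries, and that of the NF-kB targets 0.75 and 0.69.

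Across all genes, 4470 were higher and 2076 lower in the AKIRIN2 than in the PSMA3 libraries at a limma Benjamini-Hochberg adjusted p under 0.05, and 46 and 102 of these differed by at least 1 on the log2 scale. The share of higher calls was 68.3%, against 3111 higher and 3108 lower genes under median-of-ratios scaling, a share of 54.6% with quantile normalization and 51.4% after a correction for GC content and length, so the balance of directions rests on the scaling.

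The responses to both knockouts overlapped. Genes higher in both numbered 2601 and genes lower in both 2150, where independent lists of the same sizes would share 1150 and 960. HMOX1, GDF15 and BIRC3 were higher in both, and ASNS, EGR1, EGR3, TAGLN and PLK1 lower in both. A further 200 genes were higher in the AKIRIN2 and lower in the PSMA3 libraries, and 152 the reverse, among them GCLM and SLC7A11. Across genes, which are not independent replicates, the log2 fold changes correlated with a Pearson coefficient of 0.71 and a Spearman coefficient of 0.72. With no effect, sharing 3 simulated control libraries gave a mean coefficient of 0.50 in 100 simulated draws, from -0.61 to 0.96, and 0 genes in both lists. That 0 was near certain without an effect, so it cannot show how far shared controls raise the overlap of real calls. The values for independent lists do not allow for shared controls either. The covariance was 0.134, against a simulated mean of 0.0149 and a highest draw of 0.0594, a difference from the mean of 0.119. The 3 controls do not split into parts of at least 2 libraries, so part of the excess may come from the shared controls. Of the 4751 genes called the same way in both, 69.8% had the larger absolute change in the PSMA3 libraries. Those were harvested 1 day later, so the size of the response cannot be told apart from the day.

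**Figure D4:**
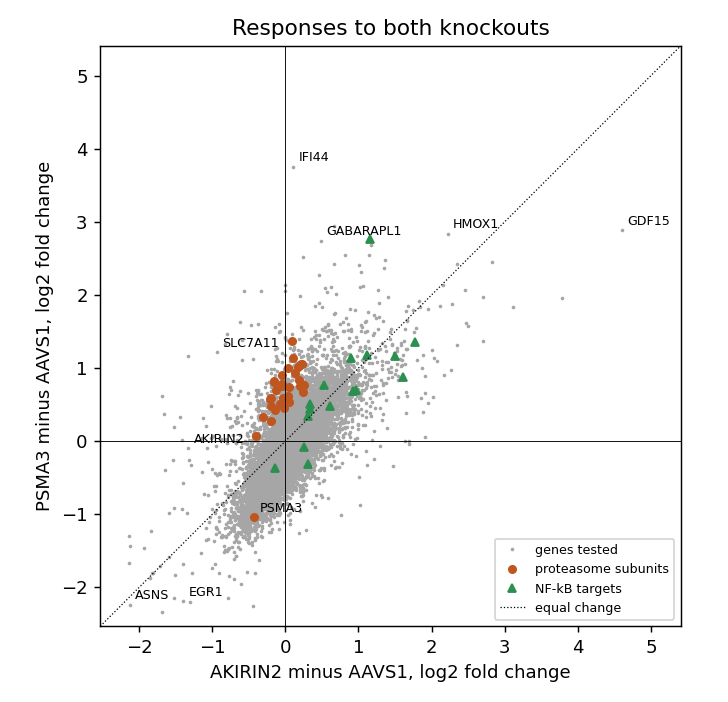
Log2 fold change on the log2(TPM + 1) scale against AAVS1 in the AKIRIN2 (horizontal) and PSMA3 (vertical) libraries for the 12218 genes tested (grey), with proteasome subunits (orange) and NF-kB targets (green) marked; the dotted line marks equal change. The Pearson coefficient across genes was 0.71, and proteasome subunits other than PSMA3 lay above the line.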

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

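The splits of libraries and the scaling test for the proteasome subunits below were chosen after the results were seen, and so was the correction for GC content and length, whose tests were otherwise set before their results.

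Of the genes called against AAVS1 in both knockouts, 352 had opposite directions, and all 352 also differed between the AKIRIN2 and PSMA3 libraries by limma with Benjamini-Hochberg adjustment. That follows almost by itself from opposite calls against the same controls, so it is not separate evidence. The heat shock chaperones were called as lower in the AKIRIN2 and higher in the PSMA3 libraries, with a median log2 difference of -0.42 between them. Against AAVS1 that list had adjusted p = 0.507 in the AKIRIN2 and adjusted p = 0.387 in the PSMA3 libraries with an estimated correlation, and adjusted p = 0.17 in the direct comparison. Its calls as a list rest on the preset correlation.

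With 3 libraries against 3 there are 10 splits, so no share under 0.05 can be had. With only the groups compared in the fit, AKIRIN2 against AAVS1 gave 5992 called genes and the highest other split 0, PSMA3 against AAVS1 gave 8034 against 1, and AKIRIN2 against PSMA3 gave 6635 against 3; in each, 1 of the 10 splits reached the real count. For lists the counts were 7 against 9 in the highest other split, with 4 of the 10 splits as large, then 14 against 13, with 1 split, and 12 against 13, with 2 splits. Splits that mix the groups and call at most 3 genes thus called up to 13 lists. Each mixed split still holds part of the difference between the groups. That part can call lists, and the rest widens the spread that the gene test uses. These counts therefore cannot show how reliable the list calls or the gene calls are. Most list calls at the preset correlation were lost with an estimated one, so they carry little weight on their own.

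Proteasome subunit mRNAs were higher in the PSMA3 than in the AKIRIN2 libraries. Scaling between libraries is argued against, since the median log2 difference of the 33 subunits, -0.68 on the TPM scale, was -0.68 with quantile normalization and -0.77 under median-of-ratios scaling. A correction for GC content and transcript length left it at -0.80. The day of harvest cannot be told apart from the target, because PSMA3 libraries shared 0 days of harvest with the others. The loss of a core subunit against the loss of AKIRIN2 stays open beside it, untested.

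Genes of GC-rich transcripts were slightly higher in the AKIRIN2 libraries, by 0.08 on the log2 scale between the upper and lower quintiles of GC content, of 2050 genes each. A GC or length bias between libraries cannot be told apart from an effect of the knockout. That difference ranged over 0.0883 among the 3 control libraries, as the test set before asked of such a bias, but the test put a range of single libraries beside a difference of means. The AKIRIN2 libraries, at 0.0717 to 0.110, all lay above the control libraries, at -0.0425 to 0.0458, and AKIRIN2 less PSMA3 was 0.148. A bias shared by the libraries of a group could not be tested. Scaling between libraries was not settled, since with quantile normalization the difference was 0.0729 with a standard error of 0.0286, less than that above the bound of 0.05 set before the test. No biological explanation was tested.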

How the results depend on the processing

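The correction for GC content and length and the 20S list without PSMA3 were chosen after seeing the data. Of 340 recomputed counts and correlations 324 stayed within 1.5 times or within their spread. With a log2 fold change of at least 1 as well, genes higher and lower were 170 and 28 for AKIRIN2 against AAVS1, 278 and 267 for PSMA3 against AAVS1, and 46 and 102 for AKIRIN2 against PSMA3, by that rule's own construction. With an estimated correlation, lists higher and lower were 0 and 0, 1 and 0, and 0 and 3. Lists lower in AKIRIN2 against AAVS1 numbered 3 in the main test, 5 without a filter on the mean, 5 with the GC and length correction, and 3 to 5 with a library left out; the cause was not tested. The 5 came without AAVS1 control replicate 2 and without AKIRIN2 knockout replicate 1. The ribosomal list in AKIRIN2 against PSMA3, not called at a median of 0.03, was called with opposite signs under quantile normalization (0.0522) and median-of-ratios scaling (-0.06). It was also called as lower after the GC and length correction (median -0.0705). The adjusted p in these settings, in that order, were 0.035, 0.0441 and 0.00123 (limma camera, Benjamini-Hochberg). NFE2L1 went from 0.02 to -0.0913 with the GC and length correction, past the threshold; the cause was not tested. Among single genes 84 settings ended a call, 21 made one and 1 made one with the sign changed; among lists 50, 25 and 1, of which 29 endings came from the estimated correlation. The correlation of both responses ranged from 0.69 to 0.72 with a library left out.

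With the replicate number as a block (replicate block), calls were 3622 and 2539, 3682 and 4396, and 4331 and 1999. The S phase list in AKIRIN2 against AAVS1 became called (adjusted p = 0.0312), and the beta-catenin list and NKD1 in PSMA3 against AAVS1 and NFE2L2 and CTNNB1 in AKIRIN2 against AAVS1 passed no more (adjusted p = 0.0543, 0.0644, 0.0648 and 0.0559, limma, Benjamini-Hochberg); no other call of a named gene or list changed. Same-numbered libraries correlated at -0.148 to 0.0299 and others at -0.0818 to 0.127, and 0 of 9 libraries correlated best with their own number in both other groups. All 3 AAVS1 libraries did so among the PSMA3 libraries, but weakly (0.0203, 0.00712 and 0.0299), so the numbers were not taken to pair the samples. TPM keeps no depth, so no limit from read number can be given.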

Other observations

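The lysosomal and synthetase lists below were made after the first results were seen but before their own tests; the chromosome 14 test, the chromosome 6 test after correction against AAVS1, the windows for AKIRIN2 against AAVS1 and the windows after correction were chosen after the results were seen.

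Lysosomal genes were followed up because GLA, alpha-galactosidase A, went from 54.6 ± 0.609 to 238 ± 10.6 TPM (SD, n = 3) in the PSMA3 libraries, 4.35 times as much. Of 29 other lysosomal genes 22 rose and 4 fell in the PSMA3 libraries, with a median of 0.37. In the AKIRIN2 libraries 16 rose and 2 fell, with a median of 0.24 and p = 0.209 with an estimated correlation (limma camera). In the PSMA3 libraries CTSD, a lysosomal protease, rose by 1.56 ± 0.06, the proton pump subunit ATP6V1A by 1.45 ± 0.05 and the cholesterol transporter NPC1 by 1.27 ± 0.05. The hypothesis of a rise of lysosomal genes as a set was not settled: the list had p = 0.0855 there with an estimated correlation (limma camera), 0.171 after adjustment over the lists made later. That p met the bound set before the test for rejecting the hypothesis, but the bound was badly chosen, since a p that misses a threshold excludes nothing while 22 of 29 members rose.

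Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were followed up because ASNS, PHGDH and PSAT1 were among the lowest genes. Synthetases of the ATF4 list were left out. Of 17 genes 11 fell and 3 rose in the AKIRIN2 libraries, with EPRS at -0.43 ± 0.03 and SARS at -0.43 ± 0.05, while QARS rose by 0.35 ± 0.03. The list was lower with p = 0.0107 with an estimated correlation (limma camera), 0.0214 after adjustment over the lists made later. That met the bound of 0.05 set before the test, and a wider fall of amino acid genes in the AKIRIN2 libraries stays a hypothesis. In the PSMA3 libraries 12 fell and 5 rose, with p = 0.203 with an estimated correlation.

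Genes on chromosome 6 telomeric of AKIRIN2 were lower in the AKIRIN2 libraries: their median log2 fold change against AAVS1 was -0.08 over 183 genes, against 0.07 over 270 genes of the p arm. Against PSMA3 the medians were -0.01 and 0.11. The 42 genes of the q arm centromeric of AKIRIN2 were at 0.0825 against AAVS1 and -0.0346 against PSMA3. After the correction for GC content and length they were at 0.0479 and -0.0457. Against PSMA3 the low medians on the q arm thus did not begin at AKIRIN2. The PSMA3 libraries were, however, themselves at 0.0903 against AAVS1 for these 42 genes. In the comparison of AKIRIN2 with AAVS1 the low median was confined to the telomeric segment, at -0.0840 before and -0.106 after the correction. Against AAVS1 the difference between the telomeric segment and the p arm was -0.15 before and -0.114 after the correction for GC content and transcript length, with a bootstrap SD of 0.0380. Library by library, the uncorrected difference relative to the control mean was -0.1345 to -0.1515 in the AKIRIN2 libraries. It was -0.0444 to -0.0144 in the PSMA3 libraries and -0.00164 to 0.00308 in the control libraries. The bootstrap resampled genes within a segment as if independent, so its SD holds no spread between libraries or regions. Within that limit, the difference left after the correction argues against GC content and length as the whole cause of the difference from AAVS1. For AKIRIN2 against PSMA3 GC content and length cannot be told apart from it, because after the correction the difference was -0.0544 on the log2 scale relative to the p arm, with a bootstrap SD of 0.0306. Ordinary regional variation cannot be told apart either. Before the correction 0% of 5741 overlapping windows of as many genes on other chromosomes had a median as low in either comparison, though the lowest window against AAVS1 was at -0.0805 beside -0.0840 for these genes. That met the bound set before the test for rejecting regional variation, but the bound ignored GC content and length. After the correction 4.63% of windows were as low against PSMA3 and 0.244% against AAVS1, and 17.1% and 5.14% were as low as the median of these genes plus its bootstrap SD. Only 41 windows of that size without overlap fit on the other chromosomes, so these shares rest on few separate stretches. Loss of the chromosome arm telomeric of the guide's target may contribute in some cells. The matching test on chromosome 14 around PSMA3, for AKIRIN2 against PSMA3, gave 0.0363 with a bootstrap SD of 0.0317. That reaches the bound of 0.03 set for it but is too wide to decide. Against AAVS1 the AKIRIN2 libraries, not targeted on chromosome 14, had medians of 0.0997 centromeric and -0.00408 telomeric of PSMA3. After the correction these were 0.0527 and -0.0384. The PSMA3 libraries had uncorrected medians of -0.0112 and -0.116. A lower telomeric median thus also arose on an arm that was not targeted.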
